A study of Mus musculus with 5 samples.

How the data were processed

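RNA of sorted splenic NK cells was sequenced from 3 control and 2 MycKO samples. Per the labels' protocols, sorted cells were lysed directly, RNA was extracted with a micro-scale column kit, and strand-specific libraries were made with a dUTP kit and sequenced as single reads on a HiSeq 1000. Per the submitters' processing notes, the tools were TopHat and edgeR, named without a role, and the genome build was mm10. Versions, the annotation, the counting tool and the use of strand are not given in the sources used here. Overlapping and antisense genes can therefore not be told apart with certainty.

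The deposited table holds 1 row per gene for 13004 genes. Per the file headers, it gives an RPKM value per sample, the authors' mean normalized signal over all samples and per group, the authors' ratio (fold change) and its log2 value, and the authors' p-value and adjusted p-value. The header does not say which program gave these p-values, and its column names are not those edgeR usually writes, so the authors' test is not known here. The columns of individual samples were matched to samples by the sample names in the labels. The lowest mean normalized value was 2.1, so genes of very low level were left out before deposit.

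The test planned before the data were examined was for counts. The table held no counts per sample, so the test fixed beforehand for other units was used. RPKM values were analysed as log2(RPKM + 1), and genes with at least 1 RPKM in at least 2 samples were kept, which left 11190. limma 3.58.1 in R 4.3.3 was fitted with the 2 groups over all 5 samples and a variance trend (3 residual and 4.41 prior degrees of freedom). All tests were two-sided, Benjamini-Hochberg adjusted p-values were taken over all genes tested, and the threshold was 0.05. Fold changes are given on the log2(RPKM + 1) scale, MycKO minus control, unless limma-voom or the authors' table is named. That scale understates changes of genes at low level. Values of limma-voom are on the log2 scale of reads scaled to the library total, and those of the authors' table are their own log2 ratios.

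RPKM values and group means together allow the reads behind each value to be worked out, because the group mean is a weighted mean of the samples' values. All values (100% in each sample) came out whole within 0.0001 of a read. The totals over listed genes were 15050801, 17610826, 14290690, 5451728 and 13337084 reads in controls 1, 2 and 3 and MycKO 5 and 6. These reads gave depth, shares of reads, transcript lengths and 1 alternative test (limma-voom). No pair of samples agreed within counting noise: the chi-square statistic per degree of freedom over genes was at least 17.8.

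Before the data were examined, 25 gene lists were fixed, 19 of pathways and NK cell states and 6 of markers of other cells. They were tested with camera in limma (preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists), with camera using an estimated correlation, and with fry. Counts of members are given over all genes tested and adjusted over the list alone. The genes named are Myc and Ncr1, the 8 largest rises and 8 largest falls among genes that passed, had an average of at least 3 on the log2 scale and showed no overlap between groups (without predicted genes, pseudogenes and antigen receptor segments), the 3 members with the smallest p of each of the 19 lists (except those not reported here), and the most abundant member of each of the 6 marker lists. Other genes named were chosen after their values were seen. Coordinates are from GENCODE vM21, which is on the mm10 (GRCm38) assembly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

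The procedure was tested on simulated data for the MycKO minus control comparison, with 13004 genes, 200 of them changed in each of 5 runs, a dispersion of 0.05 and the depths of the real samples. The test called 4.12% of genes changed by 0.5 on the log2 scale, 38.31% of those changed by 1, 98.37% of those changed by 2, and 0.11% of unchanged genes. In number, 61 unchanged genes were called, beside 10, 95, 242 and 244 of those changed by 0.5, 1, 2 and 3. False calls were thus a larger share of all calls than the threshold of 0.05. The dispersion was set and not estimated from these data.

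Alternatives tried were median-of-ratios and upper-quartile scaling, a pseudocount of 0.1, no filter, a filter of at least 5 CPM (reads scaled to the library total) in at least 2 samples, leaving out each sample, limma-voom, an adjusted p under 0.01, a log2 fold change of at least 1, camera with an estimated correlation, and fry. After seeing the data, the authors' deposited adjusted p-values and a fit with the mean level of the myeloid list as a covariate were added. RPKM is already scaled by library totals, so totals alone were no further alternative.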

Results

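RNA was sequenced from natural killer (NK) cells of the mouse spleen, innate lymphocytes that kill infected or transformed cells. The cells had been sorted by flow cytometry as live CD3-negative, NK1.1-positive, DX5-positive cells from 8-week-old C57BL/6 mice. There were 3 control libraries from mice with loxP-flanked Myc alleles (replicates 1, 2 and 3) and 2 MycKO libraries from mice in which Cre recombinase driven by Ncr1 deleted Myc (replicates 5 and 6). The genotypes given for the controls name no Cre, so the Cre allele and the loss of Myc differed together between the groups. The values analysed were RPKM, reads divided by transcript length and library total, for 13004 genes. The reads in these genes came to 15050801, 17610826 and 14290690 in controls 1, 2 and 3, and to 5451728 and 13337084 in MycKO 5 and 6, so values of MycKO 5 carried more counting error. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these samples, which may be technical.

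The comparison asked which transcripts differ in splenic NK cells when Myc is deleted. Myc itself, which encodes the MYC transcription factor (Entrez 17869; mm10 chromosome 15, 61985391 to 61990374, plus strand, protein-coding), was measured at 12.98, 22.97 and 21.24 RPKM in controls 1, 2 and 3 and at 12.5 and 8.70 RPKM in MycKO 5 and 6. Its mean was 19.1 ± 5.34 RPKM (SD, n = 3) in controls and 10.6 ± 2.68 RPKM (SD, n = 2) in MycKO. The log2 fold change was -0.77 (SE 0.28) with a limma adjusted p of 0.297, so the difference did not pass the test, although both MycKO libraries lay below all 3 controls. The value covers the whole gene and counts reads of any exon outside the deleted part, which is not given in the sources used here, so it cannot show how complete the deletion was. Ncr1, the NK receptor gene NKp46 whose regulatory sequence drives the Cre (chromosome 7, 4337724 to 4345164, plus strand), was at 1264 ± 345 RPKM (SD, n = 3) in controls and 688.5 ± 78.7 RPKM (SD, n = 2) in MycKO, with a log2 fold change of -0.84 and an adjusted p of 0.143. Without control 2, Ncr1 passed, at -1.05 with a limma adjusted p of 0.0265. In the authors' deposited test it passed with all 5 libraries, at -0.94 with an adjusted p of 0.000689.

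**Figure D1:**
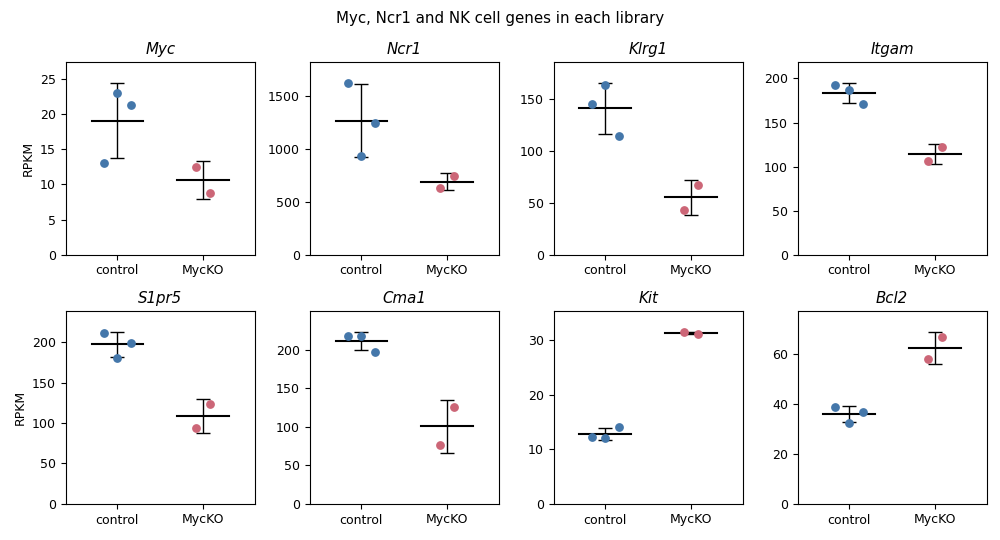
RPKM of Myc, Ncr1 and 6 further NK cell genes in each library, with controls in blue and MycKO in red. Points are libraries, horizontal lines are group means and bars are SDs (3 controls, 2 MycKO); Klrg1, Itgam, S1pr5 and Cma1 lay lower in both MycKO libraries than in each control, and Kit and Bcl2 lay higher.

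Of 11190 genes tested, 150 changed at a limma adjusted p under 0.05, of which 139 were higher and 11 were lower in MycKO. The 8 largest falls among well-measured genes were St5 (log2 fold change -1.67), the adhesion molecule gene Mcam (-1.46), the inhibitory receptor gene Klrg1 (-1.35), the mast cell protease gene Cma1 (-1.11), the ribosomal protein-like gene Rpl22l1 (-0.89), the sphingosine 1-phosphate receptor gene S1pr5 (-0.86), the arsenite methyltransferase gene As3mt (-0.83) and the small GTPase gene Arl4d (-0.73). Besides these and Itgam, the small RNA genes Snord33 (-3.41) and Mir6935 (-4.31) fell, to 0 RPKM in both MycKO libraries. In controls they were at 10.7 ± 6.45 and 23.77 ± 16.65 RPKM (SD, n = 3). Snord42a, also a small RNA gene, rose by 3.70, from 0.984 ± 1.7 to 20.9 ± 10.7 RPKM. All of them were chosen after their values were seen, as their level was under the minimum for naming. Among well-measured genes, the 8 largest rises were led by the carbonic anhydrase gene Car1 (5.09), the neutrophil calcium-binding protein gene S100a8 (3.16) and Cd24a (3.12). Next came the red pulp macrophage transcription factor gene Spic (2.88), the antibody joining chain gene Jchain (2.85) and the complement gene C1qc (2.57). The T cell receptor complex gene Cd3g (2.53) and the adhesion molecule gene Vcam1 (2.49) completed them. The number of changed genes was 35 without control 3, 39 without control 1 and 217 without control 2. Of 22 named genes that changed, Car1, Cd3g, C1qc and Spic passed without each library in turn, and the other 18 lost the call without at least 1 library. Bcl2, Itgam, Rpl22l1 and S100a8 lost it whichever library was left out. S100a8 also lost it under median-of-ratios scaling (adjusted p = 0.0561), upper-quartile scaling (0.0523), a pseudocount of 0.1 (0.0744) and no filter (0.0626), and Rpl22l1 with that pseudocount (0.0664), no filter (0.0522) and limma-voom (0.112). In 29.1% of the tested genes the groups did not overlap, against 20% by chance.

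Genes of mature, CD11b-positive NK cells were lower in MycKO. Of 16 measured members of that list, 4 fell over all genes tested and 10 fell adjusted over the list alone, and none rose. Klrg1 (Entrez 50928; chromosome 6, 122270596 to 122282882, minus strand) dropped from 141.2 ± 24.5 RPKM (SD, n = 3) to 55.4 ± 16.7 RPKM (SD, n = 2), with an adjusted p of 0.034. S1pr5 (chromosome 9, 21242912 to 21248443, minus strand), whose product guides NK cells out of lymphoid organs, dropped from 197.5 ± 15.4 to 108.9 ± 21.2 RPKM. Itgam (chromosome 7, 128062640 to 128118491, plus strand), which encodes CD11b, dropped from 183.7 ± 11.2 to 114 ± 11.5 RPKM, a log2 fold change of -0.69 with an adjusted p of 0.0387. Cma1 (chromosome 14, 55941451 to 55944675, minus strand) dropped from 211.3 ± 11.9 to 100.6 ± 34.8 RPKM, with an adjusted p of 0.0496. The gene of the transcription factor T-bet, Tbx21, was at 204.9 RPKM in controls and 140.3 RPKM in MycKO and passed adjusted over the list alone. The list's median log2 fold change was -0.50 with a camera adjusted p of 6.87e-11, and adjusted p = 0.227 with an estimated correlation. Klrg1, Itgam, S1pr5 and Cma1 kept their direction but lost the call without control 1, control 3 or MycKO 5, where Klrg1 was at -1.33, -1.49 and -1.05 with adjusted p-values of 0.118, 0.0732 and 0.168. Itgam and Cma1 lost it without control 2 as well, and Itgam without MycKO 6. All 4 also lost it with a pseudocount of 0.1 (adjusted p-values of 0.0509 to 0.0739), and Cma1 with no filter (0.0601). Markers of other spleen cells were higher in the same libraries, with a median of 2.16 for the myeloid list.

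Genes of immature NK cells were higher as a list. Of 14 measured members, 1 rose over all genes tested and 6 rose adjusted over the list alone. Kit, the stem cell factor receptor gene (chromosome 5, 75574916 to 75656722, plus strand), rose from 12.8 ± 1.15 RPKM (SD, n = 3) to 31.3 ± 0.216 RPKM (SD, n = 2), with a log2 fold change of 1.23 and an adjusted p of 0.0214. Without control 1, control 3, MycKO 5 or MycKO 6 it lay at 1.20 to 1.30 and missed the threshold, with adjusted p-values of 0.0579 to 0.144. Il7r, the interleukin 7 receptor gene, was at 11.5 ± 2.3 and 42.7 ± 21.6 RPKM (adjusted p = 0.0532), and the lymphotoxin gene Ltb at 67.6 ± 19.6 and 142.9 ± 14.7 RPKM (adjusted p = 0.0855). Il7r passed with the filter on CPM (adjusted p = 0.036), in limma-voom (0.00407) and without MycKO 5 (2.26, adjusted p = 0.0284), and Ltb passed in limma-voom (0.0167) and without control 2 (0.85, adjusted p = 0.0289). The list's median was 0.42 with a camera adjusted p of 2.92e-05, and adjusted p = 0.436 with an estimated correlation. Markers of type 1 innate lymphoid cells, relatives of NK cells, were also higher, and this list shares Il7r with the immature list. Of its 8 measured members, 1 rose over all genes tested (Tmem176b, 1.93 ± 0.596 to 12.1 ± 1.61 RPKM) and 5 rose adjusted over the list alone. Its median was 1.65, with a camera adjusted p of 1.97e-06, and adjusted p = 0.164 with an estimated correlation. Myeloid, T cell and B cell markers were higher in the same libraries, with medians of 2.16, 1.49 and 1.00. So were basophil and mast cell markers (1.68) and red cell and platelet markers (1.38). T cells are known to express Il7r and Ltb as well. Whether the rises of Kit and Tmem176b came from NK cells or from these other cells was not tested.

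NK lineage transcription factors and receptors were slightly lower as a list, with 16 of 25 measured members lower and 9 higher in MycKO. None passed limma, over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and limma-voom called 0. The authors' deposited test called 1, Ncr1. The members with the smallest p were Ncr1, the DX5 antigen gene Itga2 (-0.36) and the activating receptor gene Cd226 (0.81). The median was -0.11 with a camera adjusted p of 0.0407, and adjusted p = 0.66 with an estimated correlation, and the list did not pass without control 1 (median -0.056, adjusted p = 0.158), control 3 (-0.039, 0.222) or MycKO 5, where the median turned to 0.14 (0.835). It also missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0523) and with the filter on CPM (0.0654). Of 21 effector genes, only the lysosomal membrane gene Lamp1 rose over all genes tested, from 91.1 ± 2.52 RPKM (SD, n = 3) to 165.3 ± 1.06 RPKM (SD, n = 2; adjusted p = 0.0131, and 0.056 to 0.0917 without control 1, control 3, MycKO 5 or MycKO 6), and 5 rose and 3 fell adjusted over the list alone. The perforin gene Prf1 was at 499.3 ± 40.5 and 353.2 ± 29.9 RPKM, and the granule proteoglycan gene Srgn at 360.3 ± 23.7 and 482.4 ± 34.8 RPKM, both past the threshold adjusted over the list alone. The effector list did not pass camera (median -0.12, mean 0.09, adjusted p = 0.432). The fall of the NK lineage list rested on MycKO 5, where it took 1.51% of the reads. It took 1.87% in MycKO 6, against 1.58% to 1.89% in controls. In the MycKO libraries, both of which lay above each control for Lamp1, the marker medians of myeloid cells (2.16), T cells (1.49) and B cells (1.00) were higher. So were the lysosomal genes Ctsb (1.51), Cd68 (1.47), Lgmn (1.82) and Hexa (0.81), which were chosen after their values were seen and rose over all genes tested.

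Survival genes included a rise of Bcl2, which encodes an inhibitor of apoptosis (chromosome 1, 106538178 to 106714274, minus strand), from 36.1 ± 3.29 RPKM (SD, n = 3) to 62.6 ± 6.43 RPKM (SD, n = 2), with a log2 fold change of 0.78 and an adjusted p of 0.0471. The call was lost without each of the 5 libraries, where Bcl2 lay at 0.68 to 0.88 with adjusted p-values of 0.06 to 0.256. It was also lost under median-of-ratios scaling (0.0622), upper-quartile scaling (0.0586) and a pseudocount of 0.1 (0.0651), and limma-voom kept it. It belongs to the lists of IL-15 and STAT5 signalling and of apoptosis and p53, and was the only member of either to pass limma over all genes. In the IL-15 list, Cish (0.658 ± 0.22 and 4.03 ± 1.52 RPKM) passed adjusted over the list alone and Socs3 (0.89) did not. That list's median was 0.18, with a camera adjusted p of 0.024, and adjusted p = 0.227 with an estimated correlation. It did not pass without control 3 (0.24, adjusted p = 0.0506) or MycKO 6 (0.14, adjusted p = 0.142). T cell markers (median 1.49, with Cd3g at 2.53), B cell markers (1.00) and myeloid markers (2.16) were higher in the same libraries. In the apoptosis list, 2 of 22 measured members rose adjusted over the list alone, Pmaip1 (0.90) did not pass, and the list did not pass camera (adjusted p = 0.347), except without MycKO 6 (median 0.19, adjusted p = 0.03, and adjusted p = 0.372 with an estimated correlation).

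Transcripts of cytosolic ribosomal proteins were slightly lower as a group. None of 71 measured members passed limma singly, over all genes or adjusted over the list alone, and 14 had an unadjusted p under 0.05. Limma-voom called 1, and the authors' deposited test called 3 as lower. In MycKO 61 were lower, among them Rpl39 (963 ± 57.9 and 721.7 ± 19.8 RPKM), Rps24 (-0.46) and Rps15a (-0.41). The median was -0.17, with a camera adjusted p of 2.72e-12, and adjusted p = 0.164 with an estimated correlation. Ribosomal proteins have many processed pseudogenes, so reads may have been divided between copies. Myeloid, T cell and B cell markers, with medians of 2.16, 1.49 and 1.00, were higher in the same libraries. In ribosome biogenesis, which MYC is known to drive, none of 30 members passed limma, 2 had an unadjusted p under 0.05 and limma-voom called 0. The median of 0.05 had a camera adjusted p of 0.805, with camera's direction down relative to other genes; the smallest p belonged to Nop14 (0.60), Gnl3 (0.50) and Heatr1 (-0.42). Without MycKO 5 the median turned to -0.13 and the list passed as lower, with a camera adjusted p of 0.0498, and adjusted p = 0.671 with an estimated correlation. The sign also turned under median-of-ratios scaling, at -0.0046 with an adjusted p of 0.771, in limma-voom, at -0.037, and in the authors' deposited table, at -0.012.

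Other gene groups tied to growth did not pass as lists with all 5 libraries. Translation factors and tRNA synthetases had a median of -0.04 (camera adjusted p = 0.106), with Eef1e1 at 0.57, Yars at -0.45 and Vars at 0.28. This list passed as lower without control 3 (median -0.11, adjusted p = 0.02, and adjusted p = 0.849 with an estimated correlation) and without MycKO 5 (-0.086, adjusted p = 0.0337, and adjusted p = 0.834 with an estimated correlation). Its median turned to 0.021 without control 2 and 0.014 without MycKO 6, where it did not pass. Nucleotide, one-carbon and polyamine enzymes had a median of -0.02 (adjusted p = 0.898), with Odc1 at 0.65, Nme2 at -0.34 and Mthfd1 at 0.52. Glycolysis genes had a median near 0 and an adjusted p of 0.898, with the lactate exporter gene Slc16a3 at 1.14, Aldoa at 0.26 and Pfkp at -0.29. Respiratory chain and citrate cycle genes had a median of 0.04 (adjusted p = 0.62), which turned to -0.0089 under median-of-ratios scaling, with Ndufs3 at 0.41, Mdh2 at 0.33 and Cycs at 0.23. Of the 97 members of these 4 lists, none passed limma over all genes or adjusted over the list alone, 6 had an unadjusted p under 0.05, and limma-voom called 0. The means of the nucleotide and glycolysis lists were above 0, at 0.13 and 0.10. Of 9 nutrient uptake genes, the transferrin receptor gene Tfrc (6.22 ± 1.41 and 20.4 ± 6.96 RPKM, adjusted p = 0.0533) passed adjusted over the list alone, and over all genes with the filter on CPM (0.0384) and in limma-voom (0.00824), Slc1a5 was at -0.23 and Slc7a5 at 0.42, and the list had an adjusted p of 0.806. In the MAX network of MYC partners, Mxd4 (-0.55) and Mycl (1.46) passed adjusted over the list alone, and Mxd1 was at -0.40. The list had a camera adjusted p of 0.239, with a median of -0.03 and a mean of 0.07. Mycl was near the floor, at 0, 0.129 and 0.0319 RPKM in controls 1, 2 and 3 and 2.80 and 1.21 RPKM in MycKO 5 and 6. Myeloid markers (median 2.16) were higher in the same libraries, and whether Mycl came from NK cells or other cells was not tested.

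**Figure D2:**
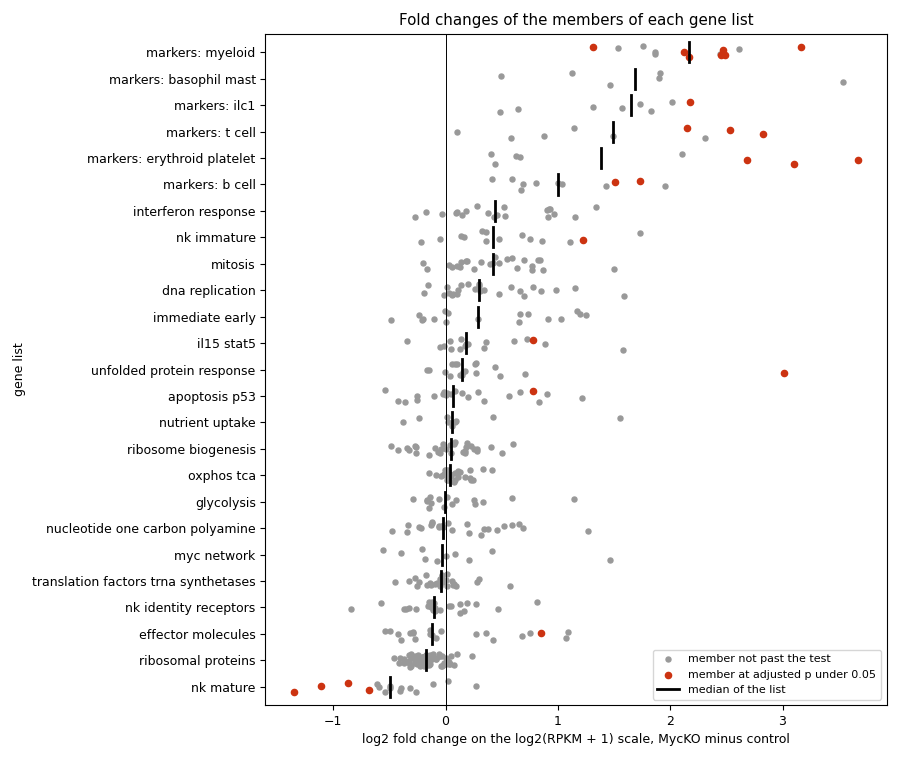
Log2 fold change, MycKO minus control on the log2(RPKM + 1) scale, of each measured member (points) of the 25 gene lists, with red for members at adjusted p under 0.05 and black bars for medians. The 6 lists of other cells' markers lie highest, with medians of 1.00 to 2.16, and genes of mature NK cells lie lowest, with a median of -0.50.

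Cell cycle genes did not pass as lists with all 5 libraries. DNA replication genes had a median of 0.30 (camera adjusted p = 0.0955), with E2f1 at 1.59, Rfc3 at 0.59 and Ccne1 at 0.99. Mitosis genes had a median of 0.42 (camera adjusted p = 0.28), with Birc5 at 1.5, Aurka at 0.82 and Ccnb1 at 0.77. Without control 2, Birc5 passed, at 2.34 with a limma adjusted p of 0.0339. Mitosis genes took 0.156% of the reads in control 2, against 0.032% and 0.0311% in controls 1 and 3 and 0.115% and 0.0538% in MycKO 5 and 6. Both lists passed camera as higher without control 2, mitosis at a median of 1.01 (adjusted p = 3.07e-08) and DNA replication at 0.54 (adjusted p = 1.47e-06), each at adjusted p = 0.479 with an estimated correlation. Both also passed without MycKO 6, mitosis at 0.89 (adjusted p = 0.000539, and adjusted p = 0.638 with an estimated correlation) and DNA replication at 0.46 (adjusted p = 0.00746, and adjusted p = 0.64 with an estimated correlation). Without MycKO 5 the mitosis median turned to -0.031 (adjusted p = 0.462). With all 5 libraries the adjusted p with an estimated correlation was 0.927 for mitosis and 0.873 for DNA replication.

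Of 18 measured genes of the unfolded protein response list, 1 rose over all genes tested and 2 rose adjusted over the list alone. Asns, asparagine synthetase, was at 0.0804 ± 0.139 RPKM (SD, n = 3) in controls and 7.72 ± 0.914 RPKM (SD, n = 2) in MycKO, with an adjusted p of 0.0131. Its call was lost without control 3 (adjusted p = 0.0559), with a pseudocount of 0.1 (0.0638) and in limma-voom (0.132), and it was not tested without MycKO 5 or MycKO 6, where the filter on RPKM removed it. Xbp1 (0.71) passed adjusted over the list alone and the chaperone gene Calr (0.27) did not. The list's median was 0.15 with a camera adjusted p of 0.0114, and adjusted p = 0.227 with an estimated correlation. It did not pass without control 2 (0.13, adjusted p = 0.0623) or MycKO 6 (0.079, adjusted p = 0.186). Interferon-induced genes had a median of 0.44 with a camera adjusted p of 0.0225, and adjusted p = 0.66 with an estimated correlation, but none of 20 members passed limma over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and limma-voom called 0. The members with the smallest p were Usp18 (0.91), Bst2 (0.92) and Rsad2 (1.34), and the list did not pass without control 1 (0.24, adjusted p = 0.158), control 3 (0.35, adjusted p = 0.0784) or MycKO 5 (0.13, adjusted p = 0.734). Beside both the unfolded protein and interferon lists, markers of myeloid cells (median 2.16), T cells (1.49) and B cells (1.00) and the antibody joining chain gene Jchain (2.85) were higher in the same libraries. Immediate early genes, induced by handling, did not pass (median 0.29, adjusted p = 0.72), with Egr1 at 0.91, Klf2 at -0.49 and Nr4a1 at 1.19.

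Markers of other spleen cells were higher in MycKO, although the sort was for CD3-negative NK1.1-positive DX5-positive cells. Of 13 measured myeloid markers, 7 rose over all genes tested and 13 rose adjusted over the list alone. Over all genes, 4 rose without control 1 or control 3 and 7 without control 2. The list's median was 2.01 to 2.38 without each library in turn. The complement gene C1qa rose from 19.7 ± 4.66 RPKM (SD, n = 3) to 112.2 ± 8.93 RPKM (SD, n = 2). The macrophage growth factor receptor gene Csf1r rose from 19.1 ± 4.57 to 87.6 ± 5.49 RPKM, while the lysozyme gene Lyz2, the most abundant member, was at 125.6 ± 84.8 and 472 ± 370 RPKM and did not pass over all genes (adjusted p = 0.265). The 14 listed myeloid genes took 0.0428% to 0.0693% of the reads in controls and 0.209% to 0.255% in MycKO. The myeloid median of 2.16 had a camera adjusted p of 1.94e-16, and adjusted p = 0.111 with an estimated correlation.

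Lymphocyte and red cell markers were higher as well. Of 11 B cell markers, 2 rose over all genes and 7 adjusted over the list alone (median 1.00; camera adjusted p of 1.16e-06, and adjusted p = 0.15 with an estimated correlation). Both, Cd74 (148.5 ± 38.5 to 424.8 ± 122 RPKM) and H2-Ab1, encode parts of the antigen presentation pathway that macrophages and dendritic cells also use. Of 9 T cell markers, 3 rose over all genes (Cd3g, Cd3e and Cd8a) and 5 adjusted over the list alone (median 1.49; camera adjusted p of 2.82e-06, and adjusted p = 0.176 with an estimated correlation), while Lat, the most abundant, was at 68 ± 16.4 and 71.7 ± 6.11 RPKM. Of 8 red cell and platelet markers, 3 rose over all genes (among them Klf1 and Slc4a1) and 5 adjusted over the list alone. The median was 1.38, with a camera adjusted p of 8.22e-06, and adjusted p = 0.29 with an estimated correlation. Car2, the most abundant, was at 99.6 ± 26 and 153.9 ± 40 RPKM. Limma-voom called 0 of the 8, and the authors' deposited test called 3. Without control 1 or control 3, limma called 1 over all genes, and leaving out each library gave medians of 1.08 to 2.66. Of 6 basophil and mast cell markers, none passed limma over all genes or limma-voom, and 2 passed adjusted over the list alone. Their median was 1.68, with a camera adjusted p of 0.00292, and adjusted p = 0.463 with an estimated correlation. The authors' deposited test called 1 of the 6, Mcpt8. The protease gene Mcpt8 was the most abundant of these, with 0 RPKM in each control, and without MycKO 5 the basophil median was 0.56 with an adjusted p of 0.948.

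**Figure D3:**
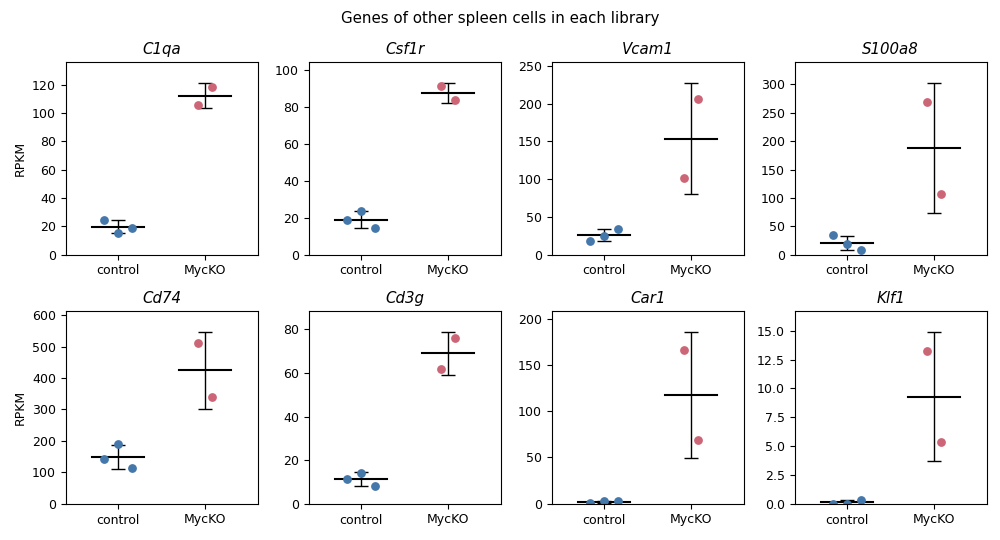
RPKM of genes of macrophages (C1qa, Csf1r, Vcam1), neutrophils (S100a8), antigen-presenting cells (Cd74), T cells (Cd3g) and red cell precursors (Car1, Klf1) in each library. Points are libraries (controls blue, MycKO red), horizontal lines are group means and bars are SDs (3 controls, 2 MycKO); both MycKO libraries lie above each control for all 8 genes.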

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

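The fit with a myeloid covariate and the authors' deposited test were chosen after seeing the data. Of the 150 changed genes (139 higher, 11 lower) the count was 80 (75 and 5) with a pseudocount of 0.1, 24 (24 and 0) at an adjusted p under 0.01, 232 (205 and 27) with limma-voom, and 442 (377 and 65) in the authors' deposited table (the program behind its test is not named in the header), which shared 141 of the 150, all in the same direction. At a log2 fold change of at least 1, 6 genes were lower. Leaving out 1 library gave 34 to 217 changed genes, 31 to 199 higher and 0 to 18 lower; where 1 MycKO library was left, it was assumed to vary like the controls. Of 22 named calls, 6, 17 and 5 were kept without controls 1, 2 and 3, and 6 and 11 without MycKO 5 and 6 (where 21 were tested, without Asns), and none of these changed sign. Klrg1, Itgam, S1pr5 and Cma1 lost their calls with a pseudocount of 0.1 and without control 1, control 3 or MycKO 5. The 13 lists passing became 0 with an estimated correlation and 7 with fry. The other scalings and filters kept each of these counts within 1.5 times. The fit with the covariate called 0 genes (0 higher, 0 lower; limma, with 458 at an unadjusted p under 0.05), because the covariate nearly repeats the groups and inflates the standard error 4.64 times. No paired analysis was possible because the groups share no replicate number. DESeq2's Wald test and TMM scaling were not run; the recovered reads were tested with limma-voom alone. MycKO 5, at 5451728 reads, limits the precision for low genes.

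Signs turned as follows. With the covariate, which nearly repeats the groups, standard errors were inflated 4.64 times and 0 genes passed. Its gene values, and the list medians made of them, are therefore too imprecise to show a change of direction. Its myeloid median is near 0 by construction, since the covariate is the mean of that list. For the other settings the cause was not tested. With the covariate, the values were Birc5 -0.21, Calr -0.41, Car2 -1.19, Ccnb1 -3.45, Ccne1 -1.15, Cd74 -0.68, Egr1 -1.09, Itga2 0.20, Lyz2 -4.51, Mcpt8 -1.12, Mdh2 -1.29, Mthfd1 -0.81, Nr4a1 -3.25, Rfc3 -0.51, S100a8 -3.49, Slc1a5 0.65, Slc7a5 -3.40, Socs3 -0.029, Srgn -0.27, St5 0.27 and Vars -0.16. List medians with it were -0.73 for ribosome biogenesis, -0.23 for respiration, -0.13 for nutrient uptake, -1.09 for DNA replication and for immediate early genes, -3.04 for mitosis, 0.79 for NK identity, -0.49 for apoptosis, -0.16 for interferon, -0.031 for myeloid, -2.11 for basophil and -0.97 for red cell markers. With median-of-ratios scaling, ribosome biogenesis was at -0.0046 and respiration at -0.0089. With limma-voom, ribosome biogenesis was at -0.037 and nucleotide synthesis at 0.0096. In the authors' deposited table, medians were -0.012 for ribosome biogenesis, -0.016 for respiration and for nutrient uptake, -0.004 for apoptosis and -0.0085 for immediate early genes. Leaving out each library gave -0.020 to 1.56 for Ccnb1, -0.11 to 0.24 for Lat and -0.26 to 1.10 for Slc7a5. For list medians it gave -0.13 to 0.24 for ribosome biogenesis, -0.11 to 0.021 for translation, -0.034 to 0.13 for nucleotide synthesis, -0.068 to 0.086 for glycolysis, -0.010 to 0.11 for respiration, -0.031 to 1.01 for mitosis, -0.27 to 0.14 for NK identity, -0.16 to 0.036 for effectors, -0.019 to 0.19 for apoptosis, -0.16 to 0.012 for the MAX network and -0.029 to 0.61 for immediate early genes.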

Other observations

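The genes of this paragraph were chosen one by one from the 150 changed genes after their values were seen, and no group of them was tested. The heme oxygenase gene Hmox1 rose by 1.91 on the log2 scale, the iron exporter gene Slc40a1 by 2.19, the biliverdin reductase gene Blvrb by 2.19 and the transferrin gene Trf by 1.76. The ferritin genes Fth1 and Ftl1, already at 204.1 ± 14.3 and 478.7 ± 26.4 RPKM (SD, n = 3) in controls, rose by 0.68 and 0.78. Cd5l (2.16), Mertk (2.09), Axl (2.15) and Mrc1 (2.29), genes known from macrophages, rose as well, as did the Rh antigen gene Rhd (2.83), Ermap (3.24) and the water channel gene Aqp1 (4.19). Among genes known from lymphocytes, Cd7 rose by 0.64 and Rgs1 by 0.86.

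In the paragraphs that follow, the tests of a lower NK cell share, of dilution and of scaling, and the test of depth for other cells' markers, were chosen only after the result was seen. Markers of other spleen cells were higher in MycKO, and shallow sequencing of MycKO 5 is argued against, since the myeloid median was 2.1 without that library. A lower share of NK cells would raise the markers of every other type alike, and the medians of 5 marker lists had a range of 1.16 (permutation p of 0.333 over their members), which does not separate alike from unlike rises. Carried-over macrophage RNA remains a candidate explanation although the sort was for NK1.1 and DX5, with Csf1r, Adgre1, C1qa, C1qb and Vcam1 rising by a similar 2.12 to 2.49. The mean correlation of these genes' deviations within groups was -0.172 (jackknife SE 0.126, from leaving out each gene). It lies below the bound of 0 set beforehand as evidence against that source, but by under 2 SE. That SE measures spread over genes and not over libraries, and 5 libraries are too few to settle it. Expression of these genes in MYC-deficient NK cells themselves was not tested.

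Genes of mature NK cells were lower in MycKO. Dilution of NK RNA by other RNA would lower NK lineage genes as much, provided that the added cells do not express them. The mature median lay -0.392 from that of the NK identity list (permutation p = 0.00071 over genes, which are not independent replicates). Without each library in turn it lay between -0.516 and -0.331 from it. This cannot decide on dilution, since expression of the identity genes in the other cells was not measured. Of these genes 9 were higher in MycKO, while Ncr1, at -0.84, lay below the mature median of -0.50. Shallow sequencing of MycKO 5 is argued against, since the mature median was -0.375 without it. A lower share of mature cells in the sorted population and lower expression per cell may both underlie the pattern, and neither was tested. The Cre allele also stays open, since no library had Cre and intact Myc.

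Ribosomal protein transcripts were lower in MycKO by a median of -0.17. Among 10000 random lists matched on length and level, 0% had a median as low, the lowest being -0.124. The matched genes were somewhat longer (median 938 against 740 bp) and less abundant (mean 8.54 against 9.05 on the log2 scale). Genes of a random list need not vary together. The ribosomal list had an estimated correlation of 0.0607, with which camera gave an adjusted p of 0.164. The 0% therefore bears on length and level alone, and is no measure of how sure the fall is. Under both other scalings, which apply the same factor to all genes of a library, the median was -0.218 or lower. The choice among these scalings thus does not account for the fall. A bias from added RNA of other cells was not tested by them, since no such factor removes it. The ribosomal median lay -0.0684 from that of the NK identity list (permutation p = 0.0342 over genes), and this difference turned to 0.16 without MycKO 6. This comparison cannot decide on dilution, since expression of ribosomal protein genes in the other cells was not measured. Dilution may contribute and cannot be told apart. An effect of MYC loss on these genes stays among the open explanations, as untested.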
